A study of Mus musculus with 24 samples.

How the data were processed

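Total RNA from the left ventricle of 24 mice was profiled on single-colour Agilent miRNA microarrays, with 1 array per animal. Per the labels, the mice were 3 to 4 months old, were non-transgenic (Ntg), carried a cardiac-specific transgene that lowers phosphoinositide 3-kinase activity (dnPI3K) or one that raises it (caPI3K), and were studied 8 weeks after coronary occlusion (myocardial infarction, MI) or open-heart sham surgery. Each of the 6 groups held 4 arrays, and the animal numbers in the titles were all different, so the arrays were taken as separate animals. Hearts were frozen, RNA was extracted with TRIzol and its integrity was assayed on a Bioanalyzer, per the labels' protocols. The labels give 2 descriptions of each sample, and these name different groups for 20 of the 24 samples and the same group for 4. The title, which also carries the animal number, set the groups; the other description was an alternative grouping. The second description runs, over the samples in order, in the order in which the series lists its groups.

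What the authors did is known in part. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, which gave for every spot a background-subtracted signal, that is, an intensity on a linear scale with no scaling between arrays. Partek 6 is named in the submitters' processing notes, and the step it was used for is not given in the sources used here. The deposited value table held the total gene signal of Feature Extraction, also a linear intensity: the values of 577 miRNA names matched the scanner files with a largest difference of 0, out of 599 names in the table. Its column medians ran from -30.9 to 17.0, so it had been neither logged, centred nor scaled between arrays. Because both hold the same values, 2 of the alternatives chosen beforehand, the total gene signal and the value table, are 1 setting.

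Each array carried 953 control spots and 11540 other spots, for 567 mouse and 10 viral miRNAs. The mouse miRNAs had 1 to 4 probes each (1672 in all), and each probe had 5 to 20 spots. No spot was saturated (0 on the 24 arrays). Control spots and the 200 to 383 spots per array that Feature Extraction marked as outliers were left out. Processed signals of the remaining spots of a probe were averaged, each array was divided by its 75th percentile over the 234 probes detected on all 24 arrays, and the probes of a miRNA were summed. Scaled sums under 0.0176 were set to that floor before the log2 transformation, which applied to 2.84% of the values tested, and values at the floor have no order among themselves. A probe counted as detected where at least a share of 0.5 of its spots were well above background. A miRNA was tested if Feature Extraction called it detected on all 4 arrays of at least 1 group, which left 173 mouse miRNAs, 133 of them detected on all 24 arrays. Viral miRNAs were not tested. Names are those of the array design. The entry named miR-199b has its probe match on chromosome 1 beside miR-199a-5p, and near-identical members of a family can bind each other's probes. Positions are those of the probe matches in the array files, on the mouse build mm9. No genome sequence was used here.

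The arrays lay on 3 slides scanned on 2 days. Slide 1 held 2 Ntg sham, 1 Ntg MI, 1 dnPI3K sham, 2 dnPI3K MI and 2 caPI3K MI arrays. Slide 2 held 2 Ntg sham, 1 Ntg MI, 1 dnPI3K sham and all 4 caPI3K sham arrays. Slide 3 held 2 arrays each of Ntg MI, dnPI3K sham, dnPI3K MI and caPI3K MI. caPI3K sham and caPI3K MI therefore share no slide. Negative-control spots had a mean net signal of 75.6 to 82.3 on slide 1 and of 446 to 566 on the other slides. Correspondingly, 245 to 288 mouse miRNAs were detected per array on slide 1 (median 267) and 148 to 182 on the others (median 170). Correlations between arrays ran from 0.969 to 0.999, and 0 pairs of arrays were identical. For these arrays, 4 per group limits the precision.

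Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values of all 24 arrays, with 6 group means and 18 residual degrees of freedom. There were 10 comparisons: MI against sham in each genotype, dnPI3K and caPI3K against Ntg within sham and within MI hearts, the differences of the MI effect of dnPI3K and of caPI3K from that of Ntg, and a slope over the 6 groups in the order given by the series (the sham groups from caPI3K over Ntg to dnPI3K, then the MI groups from caPI3K over Ntg to dnPI3K; 22 residual degrees of freedom). That order places all sham groups before all MI groups. p-values were adjusted over the 173 miRNAs by the Benjamini-Hochberg method, and a miRNA passed at an adjusted p under 0.05. Errors of fold changes are standard errors (SE) from the fit, and errors of group means are standard deviations (SD) over 4 arrays. A miRNA well above background on 0 arrays of a group has only a bound there, so its fold is given as at least the mean of the brighter group over the lowest signal measured above background on each array of the dimmer group.

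A total of 18 miRNA lists (143 members, 142 matched by name on the array, 83 tested) were fixed: striated muscle, the miR-34 family, stromal and fibroblast, the miR-29 family, the miR-30 family, smooth muscle, endothelial, leukocyte, erythroid, the family of miR-15 and miR-16, let-7, the clusters around miR-17 and miR-92a, the Dlk1-Dio3 cluster, hypoxia, the pair of miR-212 and miR-132, miR-181, and markers of other tissues (an epithelial list and a liver and neural list). Of these, 15 had at least 2 tested members and were tested with limma's fry in each of the 10 comparisons, adjusted over the 15 lists of a comparison, 150 tests in all. A fry test asks whether the members move one way on balance and does not compare a list with other miRNAs or lists. limma's camera, with an estimated or a preset correlation of 0.01, was an alternative. It compares the members of a list with the other tested miRNAs, so it asks another question than fry. An adjusted p given with an estimated correlation is that of camera. A list that passes with fry alone can still move one way. Members of the lists are also expressed by other cell types of the heart, and miR-92a is in both the endothelial list and that of the miR-17 clusters. The member with no match by name was miR-199a-3p of the stromal and fibroblast list. The entry named miR-199b, placed beside miR-199a-5p, was not taken for it, so that list was tested without this entry.

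Groups, comparisons, tests, lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. Under that rule the text names the 10 largest rises and falls among miRNAs that passed in the MI comparisons and the slope, the 6 largest each way in the genotype comparisons, the 5 with the smallest p each way in the differences of MI effects, and, where none passed, 3 each way as values. The miR-34 family, miR-21, miR-208b and miR-1 are always named, and list members where their list is described. How the last clause was applied, with the 3 largest members of a list named only where the list passed, was chosen after the files were seen, and any other miRNA named is said to have been chosen after its values were seen.

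Alternatives were the grouping by the second description, normexp background correction (offset 50) of mean and background signals, the total gene signal, the brightest probe of a miRNA, the 75th percentile over all probes, quantile normalization, the median of detected miRNAs, no filter, only miRNAs detected on all 24 arrays, a floor 4 times higher, a fit of only the groups compared, limma-trend with robust variances, slide as a block, and leaving out each array in turn. Fits without slide 1, without slide 1 and with slide as a block, and of caPI3K against Ntg sham within slide 2 were added after seeing the data.

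The fitting steps were tested on simulated data for 173 miRNAs in 50 simulations. These began at the scaled values and spread the residuals of whole arrays over the groups at random. They hold no tie of group to slide and no error of scaling, so the shares of false calls leave both out. For MI in Ntg hearts, 87.2% of 1.5-fold changes and 97.2% of 2-fold changes were recovered, and 5.33% of calls were false. For MI in dnPI3K hearts these shares were 85.2%, 96.5% and 3.89%. For caPI3K against Ntg in MI hearts they were 88%, 97.6% and 6.19%. For the difference of MI effects between dnPI3K and Ntg they were 69.5%, 90% and 4.36%. Of 1.25-fold changes, 56.9% were recovered for MI in Ntg hearts and 55.3% for MI in dnPI3K hearts. The share was 56.8% for caPI3K against Ntg in MI hearts and 30.7% for the difference of MI effects. Files were read and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.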

Results

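miRNA levels were measured in the left ventricle of 24 mice that differed in cardiac phosphoinositide 3-kinase (PI3K) activity, 8 weeks after myocardial infarction (MI) or sham surgery. PI3K signalling drives physiological growth of the heart, and the series asked how miRNA profiles change with infarction when it is lowered (dnPI3K), normal (non-transgenic, Ntg) or raised (caPI3K). Each of the 6 groups held 4 arrays. Summed mouse miRNA signal per array lay between 500108 and 1166964, and miR-1, the most abundant miRNA of cardiac muscle, gave 12.6% to 18.8% of it. Between 148 and 288 of 567 mouse miRNAs were detected per array, and 173 were tested. Slide 1, scanned on the first of 2 days, had lower negative controls (median 79.5 against 482) and a median of 267 detected miRNAs against 170 on the other slides.

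Groups are those of the sample titles throughout. For 20 of the 24 samples the labels give a second description that names another group, and all directions below hold for the titles only. Grouped by the second description, 43 miRNAs passed for MI in Ntg hearts (14 higher, 29 lower), of which 21 had also passed by title, 0 of them in the same direction. Both descriptions part the arrays into the same 6 sets of 4, so that the spread within sets is fixed to be equal and tells nothing about which is right.

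After infarction Ntg hearts had higher levels of miR-21, miR-214, miR-199a-5p and miR-34a and lower levels of muscle miRNAs. miR-21, which is enriched in cardiac fibroblasts, rose by 0.55 ± 0.18 on the log2 scale (SE, 4 against 4 arrays, adjusted p = 0.0391), from 0.69 ± 0.51 in sham to 1.24 ± 0.13 in MI hearts (SD, n = 4 each). miR-214 and miR-199a-5p, which are made from one transcript, rose by 0.68 and 0.58, and miR-34a, a target of p53, rose by 0.42 ± 0.10 (adjusted p = 0.0158). The myosin-encoded miR-499 fell by 0.48 and miR-1 fell by 0.34 ± 0.11 (adjusted p = 0.0384). All of these changes were smaller than 2-fold, the largest being 1.64-fold for miR-34b-5p (log2 fold change 0.71 ± 0.24, adjusted p = 0.0412).

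In total 36 of the 173 miRNAs passed for MI in Ntg hearts, 14 higher and 22 lower, and 60 had an unadjusted p under 0.05 where 8.65 are expected by chance. Among those higher were also miR-127, miR-222, miR-199b*, miR-199b and miR-140*, at log2 fold changes of 0.40 to 0.46. miR-127 was near background, well above it on 2 of 4 arrays in each group (0.77 within slide 1 and 0.18 within slide 2), and miR-34b-5p was well above it on 4 MI and 3 sham arrays. The lower ones included miR-133a* (-0.38), miR-30e (-0.38), miR-805 (-0.35), miR-30b (-0.33), miR-30e* (-0.33), miR-30d (-0.32), miR-133b (-0.29) and miR-30c (-0.29). miR-208b, which lies within the slow myosin heavy chain gene, did not pass at 1.03 ± 0.38 (adjusted p = 0.0537). Its sham arrays spread widely, at -2.99 ± 1.02 against -1.95 ± 0.20 in MI hearts (SD, n = 4 each). miR-34c did not pass either (0.14 ± 0.15, adjusted p = 0.532). The groups did not overlap for 27 of the 173 miRNAs, 15.6%, where chance gives 2.86%.

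Of the lists, striated muscle fell, with miR-1, miR-133a, miR-133b and miR-499 lower, 4 of 6 tested members and also 4 adjusted over the list alone (list median -0.29, adjusted p = 0.0213). miR-133a was named after its values were seen. All 5 tested members of the miR-30 family, which represses connective tissue growth factor, fell (miR-30e not past the test with slide as a block), and 5 adjusted over the list alone (median -0.32, adjusted p = 0.0213). For the miR-29 family, whose targets include collagen transcripts, the list fell (median -0.23, adjusted p = 0.0213) with 1 of 3 members past the test, miR-29c (-0.27), and 2 adjusted over the list alone. Values of miR-29b (-0.23, adjusted p = 0.474) and miR-29a (-0.17, adjusted p = 0.072) did not pass over all miRNAs. miR-29b was at -0.30 within slide 1 and 0.28 within slide 2, while miR-29a and miR-29c were below 0 within both. The miR-34 family rose, with 2 of 3 members, and 2 adjusted over the list alone (median 0.42, adjusted p = 0.0264). Of the 43 listed members of the imprinted Dlk1-Dio3 cluster only 2 could be tested, and this list passed upwards on miR-127 alone, 1 of the 2, and 1 adjusted over the list alone (median 0.29, adjusted p = 0.0213), while miR-494 was at 0.11 (adjusted p = 0.753). Against the other miRNAs, by camera with an estimated correlation, none of the 5 passed: adjusted p = 0.553 with an estimated correlation for striated muscle and miR-29, and adjusted p = 0.486 with an estimated correlation for the other 3. By camera with the preset correlation the miR-34 and miR-30 lists passed.

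Lists that did not pass for MI in Ntg hearts were stromal and fibroblast (4 of 8 members higher over all miRNAs, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0971), the miR-17 clusters (0 past, adjusted p = 0.0971) and smooth muscle (0 past, adjusted p = 0.124). The endothelial list (2 higher, 2 lower, the same counts adjusted over the list alone), let-7 and miR-181 were at an adjusted p of 0.267. Erythroid (0.34), leukocyte (0.344), the miR-15 and miR-16 family (0.476; 2 members higher, and 2 higher and 1 lower adjusted over the list alone) and the miR-212 and miR-132 pair (0.734) lay further off. The 3 lists with 1 tested member each were not tested as lists: miR-210 of the hypoxia list was at 0.33 (adjusted p = 0.102), miR-203 of the epithelial list at -0.04 (adjusted p = 0.79) and miR-128 of the liver and neural list at -0.24 (adjusted p = 0.072).

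The count for MI in Ntg hearts rested on single arrays, on the scaling and on the other groups in the fit. With only the 2 groups compared in the fit it was 4 (3 higher, 1 lower). Arrays are named here by their titles. It was 63 without NtgSham_1185 (21 higher, 42 lower), 1 without NtgSham_416, 3 without NtgSham_415 or NtgSham_1184, 2 without NtgMI_140, 17 without NtgMI_1190, 18 without NtgMI_1127 and 21 without NtgMI_1174. The split was 3 higher and 66 lower with total gene signals, which moved the median of all miRNAs by -0.22, 21 higher and 0 lower with median scaling (shift 0.12) and 13 higher and 8 lower with quantile normalization. limma called 0 with normexp (34 unadjusted), 0 with scaling over all probes (1 unadjusted) and 0 without slide 1 (10 unadjusted), and 6 without a filter. The 36 miRNAs had the same sign in each of these except for 3 under quantile normalization. With slide as a block 33 passed (15 higher, 18 lower), 31 of them also among the 36. The 5 lost were miR-30e (-0.36 ± 0.13, adjusted p = 0.0581), miR-805 (-0.25 ± 0.11, adjusted p = 0.131) and, named after their values were seen, miR-30a*, miR-26b and miR-126-5p. Within slides 1 and 2, each with 1 MI and 2 sham arrays, all 36 had the pooled sign, with miR-21 at 1.01 and 0.29, miR-34a at 0.51 and 0.36 and miR-499 at -0.68 and -0.27. Here and in the like counts below, the arrays of a slide are part of those that gave the calls. A shared sign is therefore no separate test.

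**Figure D1:**
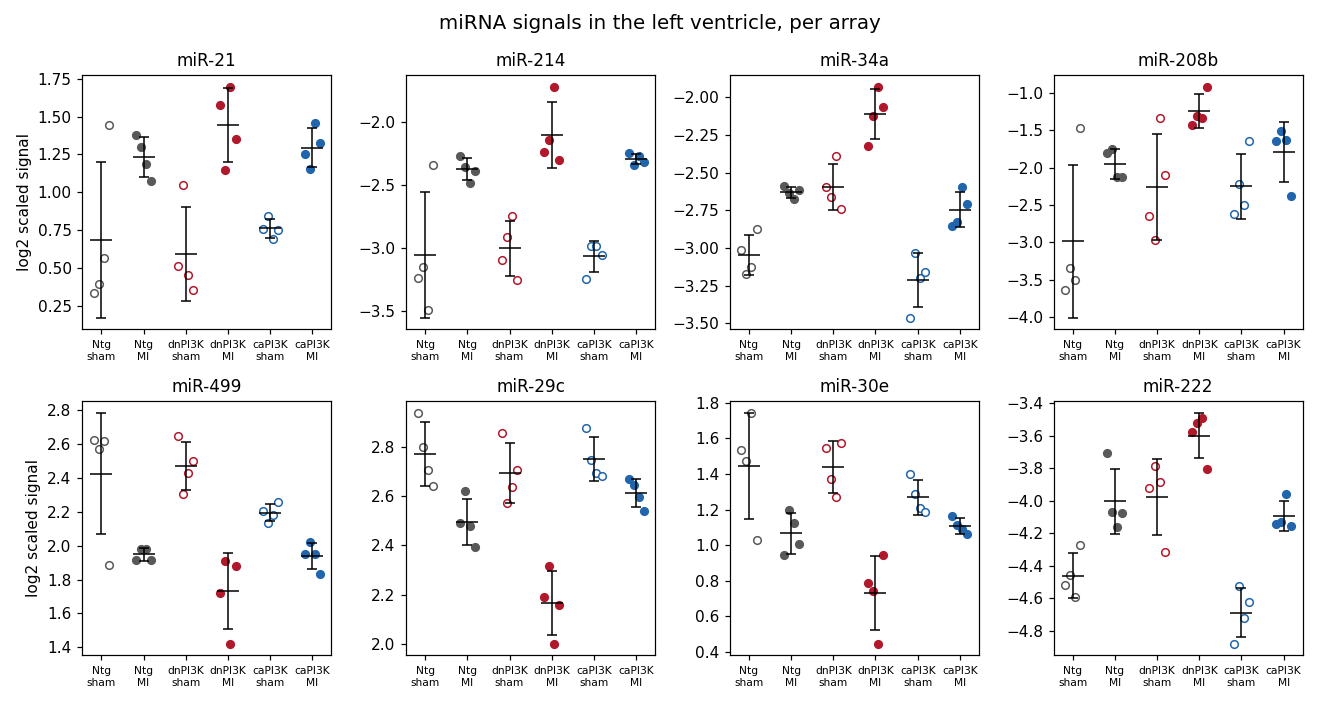
Log2 scaled signal of 8 miRNAs on each of the 24 arrays, with open points for sham and filled points for MI hearts, Ntg in grey, dnPI3K in red and caPI3K in blue, and horizontal lines and bars for the mean and SD of 4 arrays. miR-214 was higher after MI in each genotype, while NtgSham_1185 lay near the MI arrays for miR-21, miR-214, miR-208b, miR-499 and miR-30e.

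After infarction dnPI3K hearts had higher levels of miR-21, miR-214 and miR-208b and lower levels of muscle miRNAs, and for the difference of these effects from those in Ntg hearts limma called 0 miRNAs (15 unadjusted). miR-21 rose by 0.85 ± 0.18 (adjusted p = 0.000711), from 0.59 ± 0.31 to 1.44 ± 0.24 (SD, n = 4 each), miR-214 rose by 0.91 ± 0.17 and miR-208b rose by 1.02 ± 0.38 (adjusted p = 0.0309). miR-34a rose by 0.49 ± 0.10 (adjusted p = 0.000521). The heart-muscle miRNAs miR-208a, miR-499 and miR-1 fell by 1.08, 0.74 and 0.46, and miR-29c and miR-30e fell by 0.52 and 0.71, although all of these except miR-208a were above 0 with scaling over all probes. Changes of over 2-fold were found for 4 miRNAs: miR-208b, miR-208a, miR-30b* (-1.07) and miR-219 (-1.13, 2.18-fold). The last 2 were near background, well above it on 2 of 4 MI arrays each and on 3 and 4 sham arrays.

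In total 87 of 173 miRNAs passed for MI in dnPI3K hearts, 28 higher and 59 lower, with 97 at an unadjusted p under 0.05. The smallest adjusted p was 9.71e-05. The other large rises were those of miR-574-3p (0.72), miR-199a-5p (0.72), miR-199b (0.69), miR-127 (0.64), miR-199b* (0.57), miR-140* (0.55) and miR-497 (0.53), and the other large falls those of miR-145* (-0.74), miR-29b (-0.70), miR-155 (-0.69), miR-721 (-0.69) and miR-101a (-0.68). Of these miR-574-3p and miR-127 were well above background on 3 MI arrays each and on 1 and 2 sham arrays, and miR-145* and miR-721 on 2 MI arrays and 1 sham array each, with miR-721 at 0.02 within slide 1 and -1.11 within slide 3. miR-34b-5p (0.35 ± 0.24, adjusted p = 0.231) and miR-34c (0.17 ± 0.15, adjusted p = 0.328) did not pass. No overlap between groups was seen for 58 miRNAs, 33.5%, where chance gives 2.86%.

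Among the lists in dnPI3K hearts, striated muscle fell, with 5 of 6 members lower and miR-208b higher, the same counts adjusted over the list alone (median -0.44, but 0.30 over all probes, adjusted p = 0.000132, adjusted p = 0.452 with an estimated correlation). All 3 members of miR-29 and all 5 of miR-30 fell, likewise adjusted over the list alone (medians -0.52 and -0.42, but 0.22 and 0.32 over all probes, adjusted p = 5.19e-05 and 0.000132, adjusted p = 0.442 with an estimated correlation for both). Of the smooth muscle pair miR-143 fell (-0.25) while miR-145 was at -0.24 (adjusted p = 0.0702), 1 of 2 members and 2 adjusted over the list alone (list adjusted p = 0.012). Of the erythroid list miR-486, also a muscle miRNA, fell (-0.34), while miR-144 (-0.81, adjusted p = 0.0528) and miR-451 (-0.14, adjusted p = 0.552) did not pass, 1 of 3 members and 2 adjusted over the list alone (list adjusted p = 0.012). From the miR-17 clusters 5 of 9 members fell, 5 also adjusted over the list alone, with miR-19a at -0.53, miR-19b at -0.37 and miR-92a at -0.34 (list adjusted p = 0.0179). These last 3 lists did not pass against the other miRNAs by camera, at adjusted p = 0.615 with an estimated correlation. Their medians were 0.50, 0.41 and 0.48 over all probes.

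The lists that rose in dnPI3K hearts were stromal and fibroblast (4 of 8 members higher and 2 lower, 5 and 2 adjusted over the list alone, median 0.35, adjusted p = 0.0179), miR-34 (1 of 3, 1 adjusted over the list alone, adjusted p = 0.0239), the miR-15 and miR-16 family (2 of 6 higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.0239) and the 2 tested members of Dlk1-Dio3 (miR-127 alone, 1 of 2, and 1 adjusted over the list alone, adjusted p = 0.012). For all 4, adjusted p = 0.442 with an estimated correlation. The stromal members that fell were miR-10a (-0.51) and miR-450a-5p (-0.30), named after their values were seen. In the miR-15 and miR-16 family miR-497 and miR-195 (0.41) rose and miR-15a (-0.23) fell. Not past were the endothelial list (4 members higher, 3 lower, the same adjusted over the list alone, adjusted p = 0.545), the leukocyte list (2 lower, 1 adjusted over the list alone, adjusted p = 0.138), let-7 (4 higher, 4 adjusted over the list alone, adjusted p = 0.507), miR-181 (0.803) and the miR-212 and miR-132 pair (0.958). Of the single members, miR-210 rose (0.43, adjusted p = 0.0168), miR-203 fell (-0.64, adjusted p = 0.000157) and miR-128 was at -0.14 (adjusted p = 0.219).

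For MI in dnPI3K hearts the count stayed within 1.5 times when any 1 array was left out. With slide as a block 94 passed (26 higher, 68 lower), and 86 of the 87 had the pooled sign within slide 1 and 87 within slide 3, with miR-21 at 0.84 and 1.12 and miR-499 at -0.83 and -0.81. The split between higher and lower depended on the scaling. It was 43 and 40 with quantile normalization (shift of the median 0.11), 19 and 72 with median scaling and 25 and 2 with scaling over all probes (shift 0.72), and 39 passed with normexp (12 higher, 27 lower). Scaling over all probes adds the same amount to the log2 fold change of each miRNA above the floor, so it is no test of the direction of each miRNA.

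**Figure D2:**
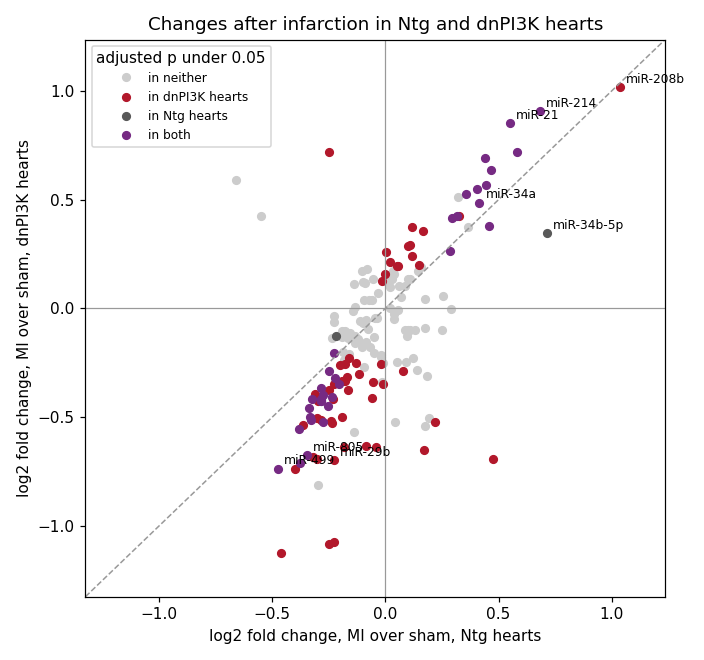
Log2 fold change of MI over sham for 173 miRNAs in Ntg (horizontal axis) and dnPI3K hearts (vertical axis), each point 1 miRNA, coloured by the genotype in which it passed, with a dashed line where both are equal. Of the miRNAs that passed in both genotypes 13 were higher and 21 lower.

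In caPI3K hearts most of the miRNAs that passed were higher after infarction. miR-214 rose by 0.77 ± 0.17 (adjusted p = 0.00366), miR-222 by 0.59 (well above background on 4 MI and 2 sham arrays), miR-34a by 0.47 ± 0.10 (adjusted p = 0.00362) and miR-21 by 0.53 ± 0.18 (adjusted p = 0.0459). miR-210, which is induced by hypoxia, rose by 0.53, a call lost with slide as a block (0.49 ± 0.19, adjusted p = 0.0958). The muscle miRNAs miR-1, miR-499 and miR-208b did not pass: miR-1 was at -0.16 ± 0.11 (adjusted p = 0.324), miR-499 at -0.26 (adjusted p = 0.169) and miR-208b at 0.46 ± 0.38 (adjusted p = 0.424). miR-34b-5p was at 0.32 ± 0.24 (adjusted p = 0.369).

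In total 33 of 173 miRNAs passed for MI in caPI3K hearts, 29 higher and 4 lower, with 57 at an unadjusted p under 0.05. Some of the largest values were near background. miR-455 was well above background on 0 of 4 sham and 3 of 4 MI arrays, at least 1.57-fold higher, and since its sham arrays were at the floor only this bound has a meaning. miR-574-3p was above it on 0 sham and 2 MI arrays, at least 1.43-fold higher, and miR-127 likewise, at least 1.17-fold higher. miR-674* (0.97 ± 0.23) was above it on 1 sham array. miR-199a-5p (0.59) and miR-199b (0.54) were also higher, and miR-494 (-0.76), miR-1224 (-0.47), miR-30c-1* (-0.42, but above 0 with normexp, and well above background on 2 arrays of each group) and miR-805 (-0.39) were lower. The groups did not overlap for 60 miRNAs, 34.7%, where chance gives 2.86%. All sham arrays lay on slide 2 and no MI array did, so this separation cannot be told from one by slide.

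The endothelial list rose in caPI3K hearts, with 6 of 10 members higher, 7 adjusted over the list alone, among them miR-222, miR-221 (0.33) and miR-27b (0.27, but below 0 with total gene signals), the last 2 not past the test with slide as a block (list median 0.18, but -0.09 with total gene signals, adjusted p = 0.00947). The stromal and fibroblast list rose, 4 of 8 members higher and 6 adjusted over the list alone (median 0.49, adjusted p = 0.0176), as did the miR-15 and miR-16 family with miR-497 (0.40) and miR-195 (0.36), 2 of 6 members and 2 adjusted over the list alone (median 0.11, but -0.16 with total gene signals, adjusted p = 0.0216), where miR-15b was at 0.20 (adjusted p = 0.142). None of these 3 lists passed against the other miRNAs by camera, at adjusted p = 0.773 with an estimated correlation. The miR-34 list (1 of 3 higher, 1 adjusted over the list alone, adjusted p = 0.101), let-7 (1 of 9 higher, 2 adjusted over the list alone, adjusted p = 0.319) and Dlk1-Dio3 (miR-127 higher and miR-494 lower, the same adjusted over the list alone, adjusted p = 0.608) did not pass. The other 9 lists had 0 members past the test without the block (limma), with adjusted p of 0.266 for striated muscle, 0.717 for miR-29, 0.319 for miR-30 and 0.811 at most.

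Because caPI3K sham and caPI3K MI arrays shared no slide, no value within a slide could be had. With slide as a block, which joins them through the other groups, 22 passed (20 higher, 2 lower), of which 18 were among the 33. The 15 lost included all 4 lower ones (miR-494, miR-1224, miR-30c-1* and miR-805) and miR-127, miR-574-3p, miR-210, miR-221 and miR-27b. The 2 lower ones, named after their values were seen, were the muscle miRNAs miR-133a (-0.31 ± 0.10, adjusted p = 0.0385, against -0.17, adjusted p = 0.171, without the block) and miR-133a* (-0.38). limma called 0 without slide 1 (35 unadjusted), 0 with scaling over all probes (8 unadjusted, shift of the median 0.12) and 6 with normexp (shift 0.14). The split was 9 higher and 47 lower with total gene signals (shift -0.27) and 23 and 10 with quantile normalization. All 33 kept their sign in each of these except for 7 with total gene signals and 1 with normexp. Without caPI3KSham_1410 or caPI3KMI_987 the count was 20.

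Of the miRNAs higher after MI, 13 passed in all 3 genotypes, among them miR-21, miR-34a, miR-127, miR-140*, miR-199a-5p, miR-199b, miR-199b*, miR-214 and miR-222. Of those lower, 1 did, miR-805, whose probe matches the mitochondrial genome (positions 16169 to 16182). Ntg and dnPI3K hearts shared 13 higher calls, where independent lists would share 2.27, and 21 lower calls against 7.50. Ntg and caPI3K hearts shared 13 higher calls against 2.35 and 1 lower call against 0.509, and dnPI3K and caPI3K hearts shared 22 against 4.69 and 2 against 1.36. These comparisons have no arrays in common but are not free of slide, since in both Ntg and caPI3K hearts slide 3 held MI arrays and no sham array. They also use the same spread of each miRNA in the fit, so the figures for independent lists may be too low. When slide was a block, Ntg and dnPI3K hearts shared 13 higher calls against 2.25 and 18 lower calls against 7.08, Ntg and caPI3K hearts 12 against 1.73 and 2 against 0.208, and dnPI3K and caPI3K hearts 14 against 3.01 and 2 against 0.786. In all 3 genotypes 11 then passed higher, without miR-127 and miR-27b, and the lower ones were miR-133a and miR-133a* in place of miR-805.

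A direct test of whether the MI effect differed between genotypes found no miRNA past the threshold. limma called 0 of 173 for dnPI3K against Ntg, with 15 at an unadjusted p under 0.05 where 8.65 are expected by chance. The values with the smallest p were those of miR-203 (-0.60 ± 0.16, adjusted p = 0.173), miR-721 (-1.17, adjusted p = 0.217) and miR-30b* (-0.85, adjusted p = 0.25) on the lower side, and of miR-574-3p (0.97), miR-328 (0.98) and let-7d* (at a larger value with an SE of 0.53) on the higher side, each of these at an adjusted p of 0.409. With the brightest probe miR-721 was at 0.02. The difference was 0.30 ± 0.26 for miR-21 (adjusted p = 0.556), 0.07 ± 0.14 for miR-34a (adjusted p = 0.781), -0.37 ± 0.35 for miR-34b-5p (adjusted p = 0.558), -0.02 ± 0.54 for miR-208b (adjusted p = 0.986) and -0.12 ± 0.16 for miR-1 (adjusted p = 0.646). miR-208a, past the test after MI in dnPI3K hearts alone, had a difference of -0.83 ± 0.37 (adjusted p = 0.409). The larger number of calls in dnPI3K hearts is thus not shown to be a difference in effect. limma called 0 with slide as a block (31 unadjusted), 10 (0 higher, 10 lower) with median scaling, which moved the median of all miRNAs by -0.18, 1 with quantile normalization, and 1 without NtgSham_1184, NtgSham_1185 or dnPI3KMI_228. Total gene signals moved the median by 0.21 and scaling over all probes by 0.77.

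For caPI3K against Ntg, limma likewise called 0 of 173 for the difference of MI effects, with 21 at an unadjusted p under 0.05. The smallest adjusted p was 0.213, shared by miR-582-5p (0.43 ± 0.12), miR-350 (0.30), miR-374 (0.46) and miR-1224 (-0.60), and miR-721 (-0.99) and miR-494 (-0.87) were at 0.24. The difference was -0.02 ± 0.26 for miR-21 (adjusted p = 0.968), 0.05 ± 0.14 for miR-34a (adjusted p = 0.844), -0.58 ± 0.54 for miR-208b (adjusted p = 0.519), 0.18 ± 0.16 for miR-1 (adjusted p = 0.5) and 0.22 ± 0.18 for miR-499 (adjusted p = 0.488). With slide as a block the count was 0 (9 unadjusted), and without caPI3KSham_1410 it was 1. Scaling over all probes moved the median of all miRNAs by 0.16. Of the 15 lists 0 passed in either difference, at adjusted p of 0.42 to 0.87 for dnPI3K and of 0.252 to 0.749 for caPI3K.

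Lower PI3K activity without infarction went with higher miR-221 and miR-222, an X-linked pair found in vascular cells. miR-221 rose by 0.89 ± 0.10 in dnPI3K over Ntg sham hearts (adjusted p = 1.5e-06), from -1.32 ± 0.09 to -0.44 ± 0.18 (SD, n = 4 each), which is 1.85-fold. miR-222 rose by 0.48 and miR-34a by 0.45 ± 0.10 (adjusted p = 0.00822). Other rises were those of miR-486 (0.45), miR-31 (0.41) and miR-203 (0.39, well above background on 3 dnPI3K and 2 Ntg arrays), and the 4 falls those of miR-805 (-0.41), miR-149 (-0.39), miR-181a (-0.33) and miR-29c* (-0.27). The endothelial list rose, with 5 of 10 members higher and 7 adjusted over the list alone, among them miR-221, miR-222 and miR-27b (0.31) (list median 0.20, adjusted p = 0.000455, adjusted p = 0.129 with an estimated correlation). miR-126-3p, known from endothelium, was at -0.13 (adjusted p = 0.398) and was named after its values were seen.

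In all, 15 of 173 miRNAs passed for dnPI3K in sham hearts, 11 higher and 4 lower, with 32 at an unadjusted p under 0.05 and no overlap for 14, 8.09% where chance gives 2.86%. miR-21 (-0.09 ± 0.18, adjusted p = 0.877), miR-208b (0.72 ± 0.38, adjusted p = 0.347), miR-1 (-0.05 ± 0.11, adjusted p = 0.894) and miR-34b-5p (0.08 ± 0.24, adjusted p = 0.913) did not pass, nor did the other 14 lists (adjusted p of 0.299 to 0.962). All 15 had the pooled sign within slide 1 and within slide 2, with miR-221 at 0.90 and 1.01 and miR-34a at 0.50 and 0.33, and 13 passed with slide as a block (10 higher, 3 lower), 10 of them among the 15. The 5 lost were miR-27b, miR-203, miR-805 and, named after their values were seen, miR-24 and miR-130a. The count was 2 without dnPI3KSham_418, 6 without NtgSham_416, 8 without NtgSham_415 or dnPI3KSham_417, 9 without dnPI3KSham_1191 or dnPI3KSham_1181, and 3 without slide 1. It was 3 (3 higher, 0 lower) with total gene signals, 5 higher and 6 lower with quantile normalization, 13 and 2 with median scaling, 1 with normexp and 0 by limma over all probes (2 unadjusted).

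After infarction dnPI3K hearts again had more miR-221, by 0.62 ± 0.10 over Ntg MI hearts (adjusted p = 0.000252), and more miR-34a, by 0.52 ± 0.10 (adjusted p = 0.00105). miR-210 (0.44), miR-127 (0.42), miR-222 (0.40) and miR-23b (0.38) were also higher. miR-721 (-0.90), miR-805 (-0.74), miR-149 (-0.51), miR-30c-2* (-0.45), miR-155 (-0.43), which is known from leukocytes, and miR-29c* (-0.41) were lower, although miR-149, miR-30c-2*, miR-155 and miR-29c* were above 0 with scaling over all probes. Some of these were near background: miR-721 was well above it on 2 dnPI3K and 1 Ntg array (-0.26 within slide 1 and -1.36 within slide 3), miR-127 on 3 and 2 (0.09 and 0.45) and miR-30c-2* on 3 each. The endothelial list rose, 6 of 10 members, with 7 higher and 1 lower adjusted over the list alone, among them miR-221, miR-222 and miR-23b (median 0.25, adjusted p = 0.00189, adjusted p = 0.202 with an estimated correlation). The miR-29 list did not pass (1 of 3 members lower, 1 adjusted over the list alone, adjusted p = 0.0558).

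In all, 20 of 173 miRNAs passed for dnPI3K in MI hearts, 11 higher and 9 lower, with 49 at an unadjusted p under 0.05 and no overlap for 24, 13.9% where chance gives 2.86%. Between the sham and the MI comparison 6 higher calls were shared, among them miR-221, miR-222, miR-34a and miR-27b, where independent lists would share 0.699, and 3 lower calls, miR-149, miR-29c* and miR-805, against 0.208. Both comparisons use the same spread of each miRNA in the fit, so these figures for independent lists may be too low. miR-21 (0.21 ± 0.18, adjusted p = 0.444), miR-208b (0.70 ± 0.38, adjusted p = 0.21), miR-1 (-0.18 ± 0.11, adjusted p = 0.277) and miR-34b-5p (-0.28 ± 0.24, adjusted p = 0.444) did not pass. The 20 had the pooled sign within slide 1 and within slide 3, with miR-221 at 0.54 and 0.64 and miR-34a at 0.36 and 0.65, and 20 passed with slide as a block (8 higher, 12 lower), 17 of them without it too. The 3 lost were miR-127, miR-210 and miR-27b. Without NtgMI_1127, NtgMI_1174 or dnPI3KMI_927 the count was 10, 11 and 13, and with only the 2 groups in the fit it was 8. It was 35 higher and 2 lower with total gene signals (shift of the median 0.21), 3 and 46 with median scaling (shift -0.13), 6 with normexp and 0 by limma over all probes (62 unadjusted, shift 0.68).

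Raised PI3K activity without infarction went with 7 lower miRNAs of 173 and 0 higher ones (36 at an unadjusted p under 0.05, limma). miR-674* was lower by log2 fold change -0.94 ± 0.23 (adjusted p = 0.0196), miR-374 by -0.44, miR-31 by -0.42, miR-221 by -0.39 ± 0.10 (adjusted p = 0.0196), miR-582-5p by -0.38 and miR-130a by -0.31, although miR-674* and miR-31 were above 0 with normexp. Both were near background, miR-674* well above it on 1 caPI3K and 3 Ntg arrays and miR-31 on 2 and 3. miR-221, miR-31 and miR-130a were the 3 that passed in opposite directions in dnPI3K and caPI3K sham hearts. The fold changes of both genotypes over Ntg sham correlated at 0.15 across miRNAs, which are not independent replicates, with a covariance of 0.00669, where 100 simulations of unchanged groups gave means of 0.51 and 0.0113. The simulations spread widely, up to 0.90 and 0.0343, and their lowest values were not recorded. The observed values are thus not shown to lie outside those of unchanged groups. With the Ntg sham arrays split so that each genotype had 2 of its own, the correlation averaged -0.13 over 6 splits (-0.26 to -0.02). In MI hearts, with the Ntg MI arrays split in this way, it averaged -0.04 (-0.30 to 0.13), and 0 miRNAs passed in both genotypes by limma, with 49 and 7 unadjusted. The endothelial list did not pass in caPI3K sham hearts (1 of 10 members lower, 1 adjusted over the list alone, adjusted p = 0.0649), nor did the other 14.

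For caPI3K in sham hearts no overlap was seen for 23 miRNAs, 13.3% where chance gives 2.86%. miR-34a (-0.17 ± 0.10, adjusted p = 0.296), miR-34b-5p (0.33 ± 0.24, adjusted p = 0.449), miR-21 (0.08 ± 0.18, adjusted p = 0.869), miR-208b (0.74 ± 0.38, adjusted p = 0.259) and miR-1 (-0.21 ± 0.11, adjusted p = 0.276) did not pass. Slide 2 alone held both groups. There limma called 0 (15 unadjusted), and 0 with slide as a block (19 unadjusted) or without slide 1 (15 unadjusted). The mean difference of the 7 miRNAs was -0.45 ± 0.07 over all arrays, -0.44 ± 0.09 within slide 2 with 4 against 2 arrays, and -0.40 ± 0.07 with the block (SE). Since the 7 were chosen on these same arrays, these means and their SE are no separate support. Without NtgSham_1185 the count was 29 (6 higher, 23 lower), without NtgSham_416 it was 2, and without caPI3KSham_1410, caPI3KSham_1413 or caPI3KSham_1416 it was 3. It was 0 by limma with median scaling (25 unadjusted), 0 over all probes (3 unadjusted, shift of the median -0.24), 1 with normexp (shift 0.15), and 1 higher and 4 lower with quantile normalization.

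After infarction raised PI3K activity went with no change that passed at this number of arrays. limma called 0 of 173 miRNAs for caPI3K against Ntg MI hearts, with 7 at an unadjusted p under 0.05 where 8.65 are expected by chance. The values with the smallest p were those of miR-29c* (0.31 ± 0.08, adjusted p = 0.0906), miR-22* (0.24) and miR-365 (0.19) on the higher side and miR-31 (-0.29), miR-709 (-0.30) and miR-221 (-0.24) on the lower side, each of these 5 at an adjusted p of 0.724. miR-34a (-0.12 ± 0.10), miR-21 (0.06 ± 0.18), miR-208b (0.16 ± 0.38) and miR-1 (-0.03 ± 0.11) were at an adjusted p of 0.961, and miR-34b-5p (-0.06 ± 0.24) at 0.974. None of the 15 lists passed (adjusted p of 0.71 to 0.747), and no overlap was seen for 9 miRNAs, 5.20% where chance gives 2.86%. miR-29c* was at 0.36 within slide 1 and 0.27 within slide 3, while miR-709 was at 0.06 and -0.52. miR-22*, miR-365, miR-31 and miR-221 kept their sign within both slides. With slide as a block the count was 0 (7 unadjusted). With only the 2 groups in the fit, or with a floor 4 times higher, 1 miRNA passed. Normexp moved the median of all miRNAs by 0.23 and total gene signals by -0.11.

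The slope over the 6 groups, in the order in which the series lists them, was tested last. miR-208b rose by 0.25 ± 0.07 per step (adjusted p = 0.00468), miR-214 by 0.22, miR-34a by 0.19 ± 0.02 (adjusted p = 7.46e-07) and miR-21 by 0.16 ± 0.04 (adjusted p = 0.000408). The muscle miRNAs miR-208a, miR-499 and miR-1 had slopes of -0.13, -0.12 and -0.08, the last 2 above 0 over all probes. Since all sham groups come before all MI groups in that order, the slope contains the MI effect. In all, 102 of 173 miRNAs passed, 42 higher and 60 lower, with 111 at an unadjusted p under 0.05. miR-455 and miR-127 also passed upwards, but both were at the floor on the caPI3K sham arrays, where the order starts, so that the size of their slopes has no meaning. Further slopes were those of miR-222 (0.19), miR-210 (0.18), miR-199a-5p (0.17), miR-674* (0.17), miR-805 (-0.21), miR-219 (-0.18), miR-30b* (-0.17), miR-145* (-0.15), miR-144 (-0.14), miR-29c* (-0.13), miR-30c-1* (-0.13) and miR-721 (-0.12). miR-34b-5p (0.09, adjusted p = 0.0848) and miR-34c (0.02, adjusted p = 0.47) did not pass.

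Of the lists, 9 of 15 had a slope that passed. Stromal and fibroblast rose (5 members higher and 2 lower of 8, adjusted p = 0.000855), as did endothelial (7 and 2 of 10, 0.00174), miR-34 (1 of 3, 0.000855), the miR-15 and miR-16 family (3 and 1 of 6, 0.0252) and the 2 tested members of Dlk1-Dio3 (miR-127 alone, 1 of 2, 0.00139, with 1 higher and 1 lower adjusted over the list alone). Striated muscle (1 higher, 5 lower of 6, 0.00535), miR-29 (2 of 3, 0.000855), miR-30 (3 of 5, 0.000855) and smooth muscle (2 of 2, 0.0018) fell, although these 4 medians were above 0 over all probes. Except for Dlk1-Dio3, the counts adjusted over the list alone were the same. None of the 9 lists passed against the other miRNAs by camera, at adjusted p = 0.678 with an estimated correlation. The 6 other lists had adjusted p of 0.104 for leukocyte and the miR-17 clusters, 0.15 for erythroid, 0.555 for let-7, 0.821 for the miR-212 and miR-132 pair and 0.947 for miR-181. With slide as a block 84 miRNAs passed (32 higher, 52 lower), 75 of them among the 102, with miR-208a, miR-144, miR-674* and miR-721 among the 27 lost and miR-34b-5p (0.17 ± 0.05, adjusted p = 0.0114) among the 9 gained. The counts were, without slide 1 and with the block 24 (14 and 10), over all probes 51 (48 and 3, shift of the median 0.11), with total gene signals 90 (24 and 66), with quantile normalization 83 (44 and 39), and with normexp 47 (23 and 24). No single array moved the count by over 1.5 times.

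Over the 10 comparisons 29 of 150 list tests passed, 16 up and 13 down. Only the endothelial list in dnPI3K hearts, sham and MI, the stromal, miR-34 and miR-30 lists for MI in Ntg hearts, and let-7 for the difference of MI effects between dnPI3K and Ntg passed against the other miRNAs by camera with a preset correlation, 6 in all and 5 of them up, and 0 passed with an estimated one. Median, mean and test of a list differed in sign in some of the lists that did not pass. The test was up with a negative median for the miR-15 and miR-16 family for MI in Ntg hearts (-0.02, mean 0.06), let-7 for MI in dnPI3K hearts (-0.01, mean 0.04), miR-34 in dnPI3K MI hearts (-0.11, mean 0.04), erythroid (-0.02, mean 0.13) and miR-30 (-0.0052, mean 0.02) in dnPI3K sham hearts, and let-7 for the slope (-0.0039, mean 0.0039). Both median and mean were negative under an upward test for Dlk1-Dio3 for MI in caPI3K hearts (-0.09) and for the difference of MI effects of dnPI3K (-0.02), erythroid in dnPI3K MI hearts (-0.01, mean -0.13), the miR-212 and miR-132 pair in dnPI3K sham hearts (-0.0075) and miR-181 for the slope (-0.0001). The test was down with a positive median for miR-29 for MI in caPI3K hearts (0.02, mean -0.03), for miR-34 in caPI3K sham hearts (0.02, mean 0.06) and for miR-34 for the difference of MI effects of dnPI3K (0.03, mean -0.09).

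The main miRNAs lie at these probe matches on the build mm9: miR-21 on chromosome 11 (86397622 to 86397641), miR-34a on chromosome 4 (149442584 to 149442603), miR-34b-5p and miR-34c on chromosome 9 (50911715 to 50911736 and 50911181 to 50911200), miR-208a and miR-208b on chromosome 14 (55567909 to 55567927 and 55594547 to 55594567), miR-499 on chromosome 2 (155448629 to 155448649), miR-1 on chromosome 18 (10785483 to 10785503), miR-214 and miR-199a-5p on chromosome 1 (164153578 to 164153590 and 164147979 to 164147997), miR-29c on chromosome 1 (196863794 to 196863815), miR-30e on chromosome 4 (120445265 to 120445281), and miR-221 and miR-222 on chromosome X (18723433 to 18723452 and 18724029 to 18724042). miR-208a, miR-208b and miR-499 are intronic miRNAs of the myosin heavy chain genes Myh6, Myh7 and Myh7b.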

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

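Except for the test of a lower share of cardiomyocytes, all tests in this part were chosen only after the results were seen. In 25 of 215 checked combinations of a named miRNA and a group of 4 arrays, 11.6%, the array at one end lay far from the other 3, where chance gives about 5%. The values are the gap to the nearest array as a share of the range of the group. On NtgSham_1185 they were, for the highest array, miR-199a-5p 0.938, miR-199b* 0.911, miR-208b 0.869, miR-34b-5p 0.898 and miR-34c 1, and for the lowest, miR-133a* 0.915, miR-30b 0.842, miR-30d 0.917, miR-30e* 0.855, miR-486 0.843 and miR-499 0.927. In Ntg MI hearts array NtgMI_1174 was lowest for miR-140* (0.892) and miR-29c* (0.836). In dnPI3K hearts the highest were dnPI3KSham_1191 for miR-34c (1), dnPI3KSham_417 for miR-574-3p (1) and dnPI3KMI_927 for miR-199b (0.861), miR-34c (0.876) and miR-497 (0.853), and dnPI3KMI_1117 was lowest for miR-574-3p (0.842) and miR-721 (0.943). In caPI3K hearts caPI3KSham_1410 was lowest for miR-199b (0.884) and highest for miR-374 (0.844), and the highest MI arrays were caPI3KMI_987 for miR-222 (0.874), caPI3KMI_1123 for miR-30c-1* (0.835) and caPI3KMI_257 for miR-497 (0.942). Where the value is 1 the other 3 arrays were at the floor.

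NtgSham_1185 stood apart from the other Ntg sham arrays in the direction of infarcted hearts. An exchange of labels with an Ntg MI array is argued against, as 0 Ntg MI arrays lay nearer to the other sham arrays in a score of 24 miRNAs called after MI in both other genotypes. A poor hybridisation of that array is also argued against: 164 miRNAs were detected on it, against 149 to 177 on the other arrays of its slide, with negative controls of 453 against 446 to 503. A single wrong label, the heart being infarcted, cannot be told apart from variation between sham animals, since the score differed by -0.00057 from the lowest Ntg MI array (the other 3 sham arrays had a mean of -1.07, SD 0.04, n = 3) and dnPI3KSham_418 was at a like score of -0.80. Variation between sham animals was not tested.

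For MI in dnPI3K hearts a lower share of cardiomyocytes in the sampled ventricle was predicted to raise the lists of all other cell types alike. The median log2 fold change was 0.35 for the stromal list, 0.05 for the endothelial, -0.14 for the leukocyte and -0.24 for the smooth muscle list, and the first exceeded the second by 0.31 ± 0.09 (SE over 1000 resamplings). This argues only against a lower share with an equal gain of all other cell types. A lower share in which stromal cells gain most would give such a difference too, so the test cannot exclude it. Members of the lists are also expressed by other cell types. The excess of lower over higher miRNAs could come from the scaling of the arrays, as the number lower minus the number higher was -23 over all probes and -3 with quantile normalization, against 27 with total gene signals and 53 with median scaling. Of these, scaling over all probes also takes in undetected probes: 234 probes were detected on all 24 arrays, against 1672 mouse probes in all. dnPI3KMI_1117 had the lowest median of deposited values (-30.9) and the highest negative controls (566). Whether this array moved that scaling was not tested. A change within cells stays open and was not tested.

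The titles and the second descriptions of the samples name different groups for the same 6 sets of arrays. The animal numbers in the titles follow the array positions on 24 of 24 arrays, which argues against titles attached to the wrong files. By titles the changes after MI correlated across miRNAs, which are not independent replicates, at 0.64 between Ntg and dnPI3K, 0.43 between Ntg and caPI3K and 0.75 between dnPI3K and caPI3K hearts, and by the second description at -0.30, -0.81 and 0.39. This favours the titles if infarction moves miRNAs alike in all genotypes, which was not tested, so that a wrong group part of the titles stays open. No biological explanation applies.

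Other splits of the arrays of each comparison into 4 and 4 were tried, all without regard to slide. For MI in dnPI3K the real split gave the most calls (1 of 35 splits gave as many miRNAs, the real one with 87, the highest other 43). A rank of 1 of 35 is the strongest that these splits can give, and 10 comparisons were tried. It therefore argues against chance without excluding it. With slide as a block 94 passed. For the slope the real order was also the largest (1 of 100, 102 and 10), but that order is tied to slide. Its first group, caPI3K sham, lay wholly on slide 2, so these splits cannot tell the order from slide. With slide as a block 84 passed, 75 of them among the 102, and 24 passed without slide 1 and with the block. For MI in Ntg the real split was also the largest (1 of 35), but only by 36 against 34, and the count was 1 without NtgSham_416, 4 with only the 2 groups in the fit and 0 by limma without slide 1 (10 unadjusted), so chance is not firmly excluded there, although 33 passed with slide as a block. The same holds for dnPI3K in MI (1 of 35, 20 and 12), where the count was 10 without NtgMI_1127, 11 without NtgMI_1174, 8 with only the 2 groups in the fit and 7 without slide 1 and with the block, although 20 passed with the block on all arrays. For MI in caPI3K the real split was also the largest (1 of 35, 33 and 1), but it is at the same time a split by slide, with all sham arrays on slide 2 and no MI array there, so the splits cannot tell the groups from slide: with slide as a block, joined through the other groups, 22 passed, and limma called 0 without slide 1 (35 unadjusted). By the number of calls chance cannot be excluded for dnPI3K in sham (2 of 35, 15 and 28), where the larger split set the 3 arrays of slide 1 and NtgSham_1184 against NtgSham_1185 and the other 3 dnPI3K arrays, and 13 passed with slide as a block. That bears on the number and not on each miRNA: miR-221 was at 0.90 within slide 1 and 1.01 within slide 2, and on the separate arrays of dnPI3K in MI 6 of the higher and 3 of the lower calls were found again, against 0.699 and 0.208 for independent lists. These figures may be too low, since both comparisons use the same spread of each miRNA in the fit. Nor can chance be excluded for caPI3K in sham (2 of 35, 7 and 18), where the larger split likewise set both arrays of slide 1 against NtgSham_1185, and limma called 0 with the block (19 unadjusted). Where the real count is 0 the splits test nothing, since each gives at least as many: this holds for caPI3K in MI (35 of 35, highest other 0) and for the differences of MI effects of dnPI3K (100 of 100 drawn, highest other 40) and caPI3K (100 of 100, highest other 0). A split with 40 calls where the real one has 0 points to a structure of the samples, and which structure was not tested.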

How the results depend on the processing

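The alternatives without slide 1, without slide 1 and with slide as a block, and within slide 2 were chosen after seeing the data, and all others were planned. Of 4473 values of the named miRNAs under the alternatives 3444 had the direction and the side of the threshold given in the report, 883 had the direction but no longer passed, 48 had it and newly passed, and 98 turned in sign. For the 29 lists that passed, 73 of 203 values were as in the report, 112 no longer passed and 18 turned in sign. Of these 116 turned values 16 passed the test, all 16 with the groups of the second description, and of the 45 over all probes 0 did. Scaling over all probes or by the median adds the same amount to the log2 fold change of each miRNA above the floor, so signs turn with that amount. Except for these, for the groups of the second description, where other arrays are compared, and for counts from fewer arrays, the cause was not tested. The fits with limma-trend and with miRNAs detected on all 24 arrays turned no sign and moved no count by over 1.5 times, nor did the linear contrast over 6 group means for the slope. Of the alternatives chosen beforehand 2, the total gene signal and the deposited value table, hold the same values and were run as 1 setting. In 85 cases an alternative gave no value: the miRNA was left out by the stricter filter or lay at the higher floor on all arrays compared, miR-34c and miR-721 had no sign with the brightest probe, and miR-1, the highest on each array, has the same value on all arrays after quantile normalization. No paired analysis was possible because each animal number occurs once. Signal over background limits the miRNAs that can be compared: 173 of 567 were tested and 133 were detected on all 24 arrays, and some, such as miR-455 and miR-574-3p in caPI3K sham hearts, lay at the floor in a whole group.

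With the groups of the second description the number of miRNAs past the test was 44 for MI in dnPI3K (19 higher, 25 lower), 91 for MI in caPI3K (30 higher, 61 lower), 37 for dnPI3K in sham (28 higher, 9 lower), 36 for caPI3K in sham (22 higher, 14 lower), 33 for dnPI3K in MI (29 higher, 4 lower), 97 for caPI3K in MI (44 higher, 53 lower), 54 for the MI effect of dnPI3K against Ntg (25 higher, 29 lower), 96 for the MI effect of caPI3K against Ntg (40 higher, 56 lower) and 0 by limma for the slope (12 unadjusted). miR-34b-5p (-0.38), miR-214 (-0.69), miR-199a-5p (-0.57), miR-21 (-0.47), miR-127 (-0.55), miR-222 (-0.68), miR-199b* (-0.53), miR-199b (-0.48), miR-34a (-0.58), miR-140* (-0.40), miR-499 (0.25), miR-133a* (0.23), miR-30e (0.20), miR-805 (0.58), miR-1 (0.13), miR-30b (0.093), miR-30e* (0.36), miR-30d (0.058), miR-133b (0.12), miR-30c (0.18), miR-208b (-0.30), miR-34c (-0.12), miR-29c (0.25), miR-29b (0.049), miR-29a (0.0018), the striated muscle list median (0.12), the miR-34 family list median (-0.38), the miR-29 family list median (0.049), the miR-30 family list median (0.18) and the Dlk1-Dio3 cluster list median (-0.060) turned in sign for MI in Ntg. miR-34a (-0.15) and miR-451 (0.0040) turned in sign for MI in dnPI3K. miR-29c* (0.017) turned in sign for dnPI3K in sham. miR-374 (0.18) and miR-582-5p (0.23) turned in sign for caPI3K in sham. miR-29c* (-0.83), miR-22* (-0.47), miR-365 (-0.49), miR-31 (0.55), miR-709 (0.029) and miR-221 (1.19) turned in sign for caPI3K in MI. miR-582-5p (-0.25) and miR-350 (-0.22) turned in sign for the MI effect of caPI3K against Ntg. miR-455 (-0.0065), miR-210 (-0.014), miR-674* (-0.074), miR-805 (0.0078), miR-29c* (0.028), miR-30c-1* (0.0039), miR-721 (0.020), miR-221 (-0.060), miR-494 (0.00076) and the endothelial list median (-0.011) turned in sign for the slope. Of 150 list tests 56 passed.

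With the 75th percentile taken over all probes the number of miRNAs past the test was 0 by limma for MI in Ntg (1 unadjusted), 27 for MI in dnPI3K (25 higher, 2 lower), 0 by limma for MI in caPI3K (8 unadjusted), 0 by limma for dnPI3K in sham (2 unadjusted), 0 by limma for caPI3K in sham (3 unadjusted), 0 by limma for dnPI3K in MI (62 unadjusted) and 51 for the slope (48 higher, 3 lower). miR-499 (0.0043), miR-30e (0.032), miR-29b (0.044), miR-155 (0.048), miR-101a (0.059), miR-1 (0.28), miR-29c (0.22), miR-29a (0.43), miR-30b (0.24), miR-30c (0.32), miR-143 (0.49), miR-145 (0.51), miR-486 (0.41), miR-451 (0.61), miR-15a (0.51), miR-19a (0.22), miR-19b (0.37), miR-92a (0.41), miR-494 (0.64), the striated muscle list median (0.30), the miR-29 family list median (0.22), the miR-30 family list median (0.32), the smooth muscle list median (0.50), the erythroid list median (0.41) and the miR-17 clusters list median (0.48) turned in sign for MI in dnPI3K. miR-149 (0.17), miR-30c-2* (0.0063), miR-155 (0.26) and miR-29c* (0.27) turned in sign for dnPI3K in MI. miR-499 (0.00066), miR-1 (0.041), miR-29c (0.014), miR-29b (0.026), miR-29a (0.095), miR-30e (0.0035), miR-30a (0.033), miR-30c (0.040), miR-145 (0.069), miR-143 (0.077), miR-15a (0.071), miR-494 (0.029), the striated muscle list median (0.050), the miR-29 family list median (0.026), the miR-30 family list median (0.040) and the smooth muscle list median (0.073) turned in sign for the slope. Of 150 list tests 2 passed.

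With the total gene signal, which is the deposited value table, the number of miRNAs past the test was 69 for MI in Ntg (3 higher, 66 lower), 56 for MI in caPI3K (9 higher, 47 lower), 3 for dnPI3K in sham (3 higher, 0 lower) and 37 for dnPI3K in MI (35 higher, 2 lower). miR-494 (-0.11) turned in sign for MI in Ntg. miR-27b (-0.0036), miR-15b (-0.073), the endothelial list median (-0.087) and the miR-15 and miR-16 family list median (-0.16) turned in sign for MI in caPI3K.

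With normexp the number of miRNAs past the test was 0 by limma for MI in Ntg (34 unadjusted), 39 for MI in dnPI3K (12 higher, 27 lower), 6 for MI in caPI3K (6 higher, 0 lower), 1 for dnPI3K in sham (1 higher, 0 lower), 1 for caPI3K in sham (0 higher, 1 lower), 6 for dnPI3K in MI (4 higher, 2 lower) and 47 for the slope (23 higher, 24 lower). miR-34c (-0.0079) turned in sign for MI in dnPI3K. miR-30c-1* (0.12) turned in sign for MI in caPI3K. miR-674* (0.12) and miR-31 (0.16) turned in sign for caPI3K in sham. miR-31 (0.31) turned in sign for caPI3K in MI. miR-34c (-0.021) turned in sign for the slope.

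With median scaling the number of miRNAs past the test was 21 for MI in Ntg (21 higher, 0 lower), 0 by limma for caPI3K in sham (25 unadjusted), 49 for dnPI3K in MI (3 higher, 46 lower) and 10 for the MI effect of dnPI3K against Ntg (0 higher, 10 lower).

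With quantile normalization the number of miRNAs past the test was 21 for MI in Ntg (13 higher, 8 lower) and 1 for the MI effect of dnPI3K against Ntg (1 higher, 0 lower).

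Without a filter the number of miRNAs past the test was 6 for MI in Ntg (4 higher, 2 lower), 19 for MI in caPI3K (19 higher, 0 lower), 6 for dnPI3K in sham (5 higher, 1 lower), 2 for caPI3K in sham (0 higher, 2 lower) and 12 for dnPI3K in MI (7 higher, 5 lower).

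With a floor 4 times higher the number of miRNAs past the test was 1 for caPI3K in MI (1 higher, 0 lower).

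With only the groups of the comparison in the fit the number of miRNAs past the test was 4 for MI in Ntg (3 higher, 1 lower), 54 for MI in dnPI3K (16 higher, 38 lower), 53 for MI in caPI3K (44 higher, 9 lower), 3 for dnPI3K in sham (2 higher, 1 lower), 3 for caPI3K in sham (0 higher, 3 lower), 8 for dnPI3K in MI (5 higher, 3 lower) and 1 for caPI3K in MI (1 higher, 0 lower).

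With slide as a block the number of miRNAs past the test was 0 by limma for caPI3K in sham (19 unadjusted).

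Without slide 1 the number of miRNAs past the test was 0 by limma for MI in Ntg (10 unadjusted), 0 by limma for MI in caPI3K (35 unadjusted), 3 for dnPI3K in sham (2 higher, 1 lower) and 0 by limma for caPI3K in sham (15 unadjusted). miR-494 (0.027) turned in sign for MI in dnPI3K.

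Without slide 1 and with slide as a block the number of miRNAs past the test was 0 by limma for MI in Ntg (11 unadjusted), 0 by limma for MI in caPI3K (20 unadjusted), 1 for dnPI3K in sham (1 higher, 0 lower), 0 by limma for caPI3K in sham (13 unadjusted), 7 for dnPI3K in MI (2 higher, 5 lower) and 24 for the slope (14 higher, 10 lower). miR-29b (0.028) turned in sign for MI in Ntg. miR-494 (0.16) turned in sign for MI in dnPI3K. miR-494 (0.019) turned in sign for the slope.

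Within slide 2 the number of miRNAs past the test was 0 by limma for caPI3K in sham (15 unadjusted).

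With the brightest probe, miR-721 (0.020) turned in sign for the MI effect of dnPI3K against Ntg.

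With camera and an estimated correlation, of 150 list tests 0 passed.

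With camera and a preset correlation, of 150 list tests 6 passed.

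Leaving out 1 array at a time gave counts of 1 to 63 for MI in Ntg, 20 to 27 for MI in caPI3K, 2 to 21 for dnPI3K in sham, 2 to 29 for caPI3K in sham, 10 to 27 for dnPI3K in MI and 0 to 1 for the difference of MI effects of dnPI3K and of caPI3K against Ntg. miR-494 for MI in Ntg ranged from -0.015 to 0.23 and miR-451 for MI in dnPI3K from -0.28 to 0.035, neither past the test with all arrays. For the other named miRNAs 0 values turned in sign when 1 array was left out, and of 2032 values 268 no longer passed and 21 newly did.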

Other observations

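All tests in this part were chosen only after the results were seen, and none was planned. Both arms were tested for 19 pairs by name, of which 17 had both arms placed at the same locus. After MI in dnPI3K hearts the changes of both arms correlated at 0.60 across these 17 precursors (two-sided permutation p = 0.0127 over 100000 permutations, Spearman 0.72 with p = 0.00147), and at 0.57 without the 2 farthest. Precursors of one family or cluster are not independent. A change at the level of the precursor is a candidate explanation.

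Neighbouring miRNAs within 10 kb also moved together after MI in dnPI3K hearts. Over 65 pairs of 69 miRNAs the median absolute difference of log2 fold changes was 0.13, against 0.39 for permuted pairs (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give), and 33 pairs were called in the same direction. Each miRNA was placed at 1 match, although some have several copies. Some of the 65 pairs, such as miR-24 with miR-24-1* and miR-30c with miR-30c-2*, are both arms of one precursor. By position this also holds for miR-199a-5p with the entry named miR-199b. These pairs are not separate neighbours. A change of the shared transcript may underlie this, although miRNAs of a cluster are often alike in sequence and may share probe signal, which was not tested.

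The 36 miRNAs called for MI in Ntg hearts were combined into a score, signed by their direction there. It shifted after MI by 0.36 in Ntg, 0.48 in dnPI3K and 0.27 in caPI3K hearts, the first being the data in which the miRNAs were chosen. A larger shift in dnPI3K than in caPI3K hearts was the hypothesis, and the difference was 0.22 (exact two-sided permutation p = 0.0592 over 4900 arrangements), so the test leaves it open. The arrangements exchanged dnPI3K and caPI3K arrays within MI and within sham hearts. The p is therefore exact only if these genotypes do not differ in the score at all, and not for equal shifts alone. The arrangements took no account of slide, and caPI3K sham and caPI3K MI arrays shared no slide.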
